A study of Homo sapiens with 8 samples.

How the data were processed

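The series holds 8 two-colour Agilent arrays of design 072363, with RNA of mock cells in Cy3 and of transfected cells of the same line in Cy5. Per the labels, cells were transfected with microRNAs or small interfering RNAs by Lipofectamine RNAiMAX, and total RNA was labelled with a low-input linear amplification kit. Per the file headers, Feature Extraction 11.5.1.1 read the scans and placed the probes on genome build hg19. The authors deposited the scanner output, in which the mean signal and the local background of each spot are raw intensity values and the processed signals are background-subtracted, dye-normalised intensity. The deposited log ratio of each spot is a log10 of processed red over green. The deposited p-value (p_value) of a log ratio comes from the software's error model for a single array. The deposited series matrix holds the same log10 ratios, and the largest difference between the 2 was 0 on 8 arrays. All arrays lie on 1 slide with 1 scan date, so that no slide term could be fitted.

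Each array had 60901 non-control spots for 58201 probes. Median raw signal per array ran from 25.2 to 29.2 in green and from 21.5 to 33.9 in red, over a background of 16 to 19. No spot was saturated. Gene symbols were updated through RefSeq accessions for 3863 probes. Raw mean signals were corrected with limma's normexp (offset 50) and normalised by loess within each array, with control spots at weight 0, to log2 of red over green. Spots of a probe were averaged. A gene was represented by its probe with the highest mean brightness, and a probe was tested where it was well above background in at least 1 colour on every array of the comparison. Tools were R 4.3.3, limma 3.58.1 and the data.table package (1.17.8).

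The treatments with 2 arrays (si-PMM2, miR-145-5p and miR-145-3p) were fitted together in limma (lmFit and eBayes) on 6 arrays with 1 coefficient per treatment and 3 residual degrees of freedom. Each coefficient was tested against 0, two-sided, with Benjamini-Hochberg adjustment and an adjusted p under 0.05. The difference of the strands had the cell line as a block, which left 2 residual degrees of freedom. The ratio against 0 leaves out the mock's own spread. The A549 and TE8 arrays served as replicates of a strand, so that differences between the lines are part of the error, and the si-PMM2 arrays are 2 different siRNAs. Nothing in the labels says which arrays came from separate cultures. The T24 arrays were described by counts at 1 or more on the log2 scale, with no test.

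The genes named in the text followed a rule: up to 10 genes in each direction with the largest mean among those past the threshold with like signs on both arrays, completed to 5 by the smaller of the 2 values where fewer passed. For T24 the 8 highest and 8 lowest genes of at least median brightness were taken, and for each list described up to 4 members with the largest values in the direction of the list. Some genes that the rule named are not used here. 27 gene lists were fixed: pathways, reported targets of the transfected strands written from background knowledge, and markers of other cell types. 12 of 15 histone genes and 12 of 14 leukocyte genes were on the array. Lists with at least 5 tested members were tested with limma's cameraPR at a preset correlation of 0.01, adjusted over lists and comparisons. Beside it stand camera at an estimated correlation and fry. At an estimated correlation no list passed in any comparison, also where that correlation was below 0.01. A call lost at this setting therefore does not by itself show that correlation among genes made the call. With miR-145-5p the estimated correlation was 0.73 for DNA replication, 0.77 for mitosis and 0.93 for interferon-stimulated genes, far above the preset. Their fry adjusted p were 0.249, 0.335 and 0.335. The small cameraPR adjusted p of such lists may therefore rest on the preset correlation. On single arrays a list's median was placed among 10000 random lists matched on brightness in 20 bins, and medians beyond the 2.5th or 97.5th percentile are described as outside the random range. Random lists were drawn gene by gene, so that their range may be too narrow for lists of genes that vary together. The comparisons, tests, rule, lists and most alternatives were chosen before the data were examined.

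The alternatives were no background correction, median centring without loess, the scanner software's ratio (centred), no filter and a filter in both colours. The deposited series matrix holds the scanner software's ratios, so it was not run apart and its counts are those of that ratio. Further alternatives were the arrays of a comparison alone, an intensity trend, no block, leaving out each array and subtraction of the mean of the treatments in other lines. For single arrays the software's p under 0.01 was also used. An offset of 1 was added after the data were examined, as were the subtraction without the miR-223-5p array, the other scalings and the left-out arrays for lists. For lists on T24 arrays, the median relative to matched random lists replaced the raw median as the value compared between settings after raw medians had been seen to turn. The pipeline was tested on simulated data made from these arrays. It recovered 96% of genes changed by 2 on the log2 scale for si-PMM2 and miR-145-5p, 93% for miR-145-3p and 80% for the strand difference, and 78%, 81%, 79% and 18% of those changed by 1. Of unchanged genes it called 15, 13, 4 and 5. The simulated noise was normal, with the moderated spread of each gene, and 100 genes of each size were changed. In the real data PMM2 at -1.04 with si-PMM2 had a limma adjusted p of 0.231. The percentages recovered may therefore overstate what the real fits could find. A planted list shift of -0.5 was found in each of the 4 comparisons, and of the other lists, 23 for si-PMM2 and 25 for each of the rest, 1, 0, 2 and 1 were called. The planted list was that of mitosis genes, which holds 4 of the 8 reported miR-145-3p targets. Simulated genes varied independently, whereas the estimated correlation within real lists reached 0.97. These counts therefore do not give the rate of false calls for lists of correlated genes. The search for microRNA sites in 3' untranslated regions was not run, because no such sequences were used here.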

Results

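Messenger RNA was measured on 8 two-colour Agilent arrays, each of which set transfected human cancer cells (Cy5, red) against mock cells of the same line (Cy3, green). The labels describe the mock cells as not transfected. T24 bladder cancer cells received miR-223-3p on 1 array and miR-223-5p on 1 array, the 2 strands cut from a single microRNA precursor. A498 renal cancer cells received 1 of 2 numbered small interfering RNAs against PMM2 on each of 2 arrays. A549 lung cancer and TE8 esophageal cancer cells each received miR-145-5p on 1 array and miR-145-3p on another. Values are log2 ratios of transfected over mock, taken after an offset of 50 was added to both signals. A value of 1 is a doubling of signal plus offset, and for a dim probe more than a doubling of signal. With an offset of 1, 547 genes in place of 159 reached 1 in either direction with miR-223-3p, and 1914 in place of 726 with miR-223-5p. Folds and percentages of mock are on the scale with offset 50 unless another setting is named. Errors are standard errors (SE) of a limma fit that pooled the spread of the 6 arrays with replicated treatments. Between 46.3% and 57.7% of the probes were well above background in at least 1 colour, and the number of arrays limits the precision. No treatment was repeated with the dyes exchanged, so any dye bias of a probe and any effect of transfection itself stay in every ratio against mock.

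The miR-145-5p comparison asked which transcripts moved in both A549 and TE8 cells after transfection of this strand. 41 of 21966 genes rose and 92 fell at an adjusted p under 0.05. CEND1, a neuronal cell cycle exit protein, rose most at 2.54 ± 0.06 (SE, n = 2 arrays, adjusted p = 0.00488), which is 5.82-fold. The myosin light chain MYL9 (2.48 ± 0.19) and the smooth muscle marker TAGLN (1.91 ± 0.14) rose, while the actin and smooth muscle list did not pass (cameraPR adjusted p = 0.695), with 2 of 23 members called higher and 3 lower. The tRNA-editing enzyme DTD1 (-2.24 ± 0.16), the lysosomal membrane protein TMEM9B (-2.22 ± 0.15) and the tight junction protein F11R (-2.12 ± 0.22) fell. The tropomyosin TPM3 fell by 1.76 ± 0.05 with an adjusted p of 0.00713.

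Among the other genes that rose were the calcium-binding protein TESC (1.43), the vasodilator peptide ADM (1.42), the histone H2AC19 (1.59), ZFHX2 (1.61), TENT5A (1.32), CCDC9B (1.23) and the membrane mucin MUC1 (1.16). Among those that fell were SIRPA, the receptor for CD47 (-2.05), the actin-binding protein TAGLN2 (-1.90), the stress granule protein G3BP1 (-1.83), the nuclear lamin LMNB2 (-1.82), the mitochondrial protein COXFA4 (-1.76) and the histone chaperone NAP1L1 (-1.65). On build hg19 the probe of CEND1 lies on chromosome 11 from 787111 to 787170, that of TPM3 on chromosome 1 from 154127780 to 154127824 and that of MYL9 on chromosome 20 from 35177541 to 35177600. Of the 53 called named genes with another measured probe, 13 had a probe with the opposite sign.

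The list of reported miR-145-5p targets fell as a group, with medians of -0.47 in A549 and -0.52 in TE8 (cameraPR adjusted p = 2.04e-09). The call was lost at adjusted p = 0.914 with an estimated correlation. Of its 34 tested members, 3 fell and 1 rose over all genes, and 17 fell and 3 rose when adjusted over the list alone. F11R (-2.12), the myosin MYO5A (-1.20) and the depalmitoylase ABHD17C (-1.20) fell, and MUC1, a member of this list, rose. FSCN1, which bundles actin in cell protrusions, had the lowest mean of the list at -3.55 ± 0.45, with -3.18 in A549 and -3.92 in TE8, and its adjusted p was 0.0615.

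Interferon-stimulated genes had far higher values in A549 than in TE8 cells after miR-145-5p, and the difference between the lines was tested over both strands only (median -1.39 for TE8 minus A549, cameraPR adjusted p = 0.00559, and adjusted p = 0.913 with an estimated correlation). The list rose (adjusted p = 5.82e-06, and adjusted p = 0.914 with an estimated correlation), with a median of 2.77 in A549 and 0.20 in TE8, and all 31 tested members had a mean above 0. With median centring in place of loess its median was 2.15 and its adjusted p 0.215. No single member passed limma's test. The antiviral proteins IFIT2, ISG15 and IFIT1 had values of 5.72, 4.86 and 4.62 in A549 and of 0.97, 1.21 and 0.84 in TE8.

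Proliferation genes fell after miR-145-5p relative to mock, and their lists did not pass as miR-145-5p minus miR-145-3p. The list of DNA replication genes had medians of -0.47 in A549 and -0.89 in TE8 (adjusted p = 5.24e-10), and that of mitosis genes had medians of -0.43 and -0.53 (adjusted p = 2.56e-07). Both calls were lost at adjusted p = 0.914 with an estimated correlation. No member passed over all genes. When adjusted over the list alone 0 of 40 mitosis genes and 14 of 36 replication genes passed, among which POLE2, PRIM1, CDC45 and UHRF1 had means of -1.39, -1.13, -1.10 and -1.29. After subtraction of the mean of the treatments in other lines the medians were 0.15 and 0.38 (adjusted p = 0.698 and 0.0894), which rested on the miR-223-5p array. With that array left out of the mean they were -0.27 and -0.11 (adjusted p = 0.0118 and 0.197). The reported miR-145-3p targets, 5 of whose 8 members are in these proliferation lists, fell too (median -0.72, adjusted p = 5.91e-08, and adjusted p = 0.914 with an estimated correlation). In that list LMNB2 alone passed over all genes, and the subtraction gave a median of -0.048 (adjusted p = 0.341), or -0.35 without the miR-223-5p array (adjusted p = 0.00678).

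Ribosomal protein genes rose slightly as a list (median 0.20, adjusted p = 0.00118, and adjusted p = 0.914 with an estimated correlation). 5 of 34 members were higher when adjusted over the list alone and none over all genes, where RPL32 at 0.38 had an adjusted p of 0.0696. The ATF4 list, which holds genes of amino acid synthesis and import, fell with a median of -0.19 (adjusted p = 0.0445, and adjusted p = 0.935 with an estimated correlation). In it the serine synthesis enzyme PSAT1 fell by 1.501 ± 0.15, and the cystine transporter SLC7A11 had a mean of -1.43 with an adjusted p of 0.0673. Without TE8 the ATF4 list had an adjusted p of 0.962 and the ribosomal list one of 0.398. With median centring, where the median of all genes was 0.33, the ATF4 median was 0.47 (adjusted p = 0.883), and with the scanner software's ratio the adjusted p of the ATF4 and ribosomal lists were 0.184 and 0.698. The ATF4 list did not pass without background correction (0.0659) or with an offset of 1 (0.113) either. After subtraction of the treatments in other lines the ribosomal median turned to -0.017 and the ATF4 median to 0.23 (adjusted p = 0.728 for both), and without the miR-223-5p array they were 0.085 and 0.12 (0.226 and 0.847). The test of the p53 targets pointed down (adjusted p = 0.0444, and adjusted p = 0.923 with an estimated correlation) although their median was 0.0060 and their mean -0.12. Without TE8 its adjusted p was 0.742, and it did not pass under any of the 4 other scalings (0.0809 to 0.269).

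With median centring in place of loess, which moved the median of all genes to 0.33, 2654 genes were called higher and 35 lower, against 41 and 92. No gene passed without the A549 array, with the 2 miR-145-5p arrays fitted alone or with the scanner software's ratio, 170 passed without TE8, 28 of them among the 133, 6 passed with no filter on dim probes and 1 after subtraction of the treatments in other lines.

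**Figure D1:**
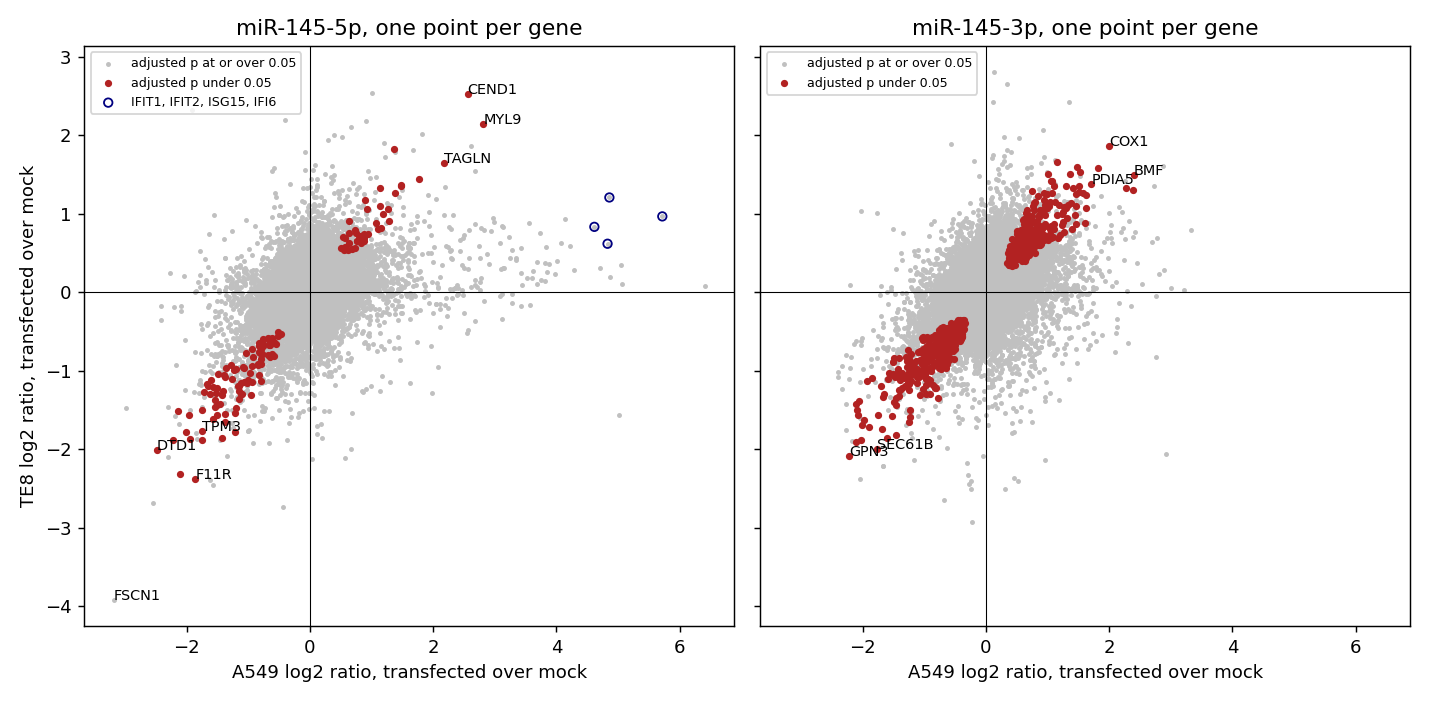
Log2 ratio of transfected over mock in A549 (horizontal axis) and TE8 (vertical axis) for miR-145-5p (left) and miR-145-3p (right), 1 point per gene, with genes at an adjusted p under 0.05 in red. CEND1 lies near 2.5 in both lines, FSCN1 lies at -3.18 and -3.92 without passing the test, and the circled interferon-stimulated genes lie far to the right, with IFIT2 at 5.72 in A549 and 0.97 in TE8.

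The miR-145-3p comparison asked the same of the other strand of the precursor. 264 of 22164 genes rose and 319 fell. The largest decreases were those of the GTPase GPN3, which takes part in RNA polymerase assembly (-2.15 ± 0.13, n = 2 arrays, adjusted p = 0.0259), the proteasome subunit PSMA1 (-2.01 ± 0.11), the mitochondrial assembly factor COA1 (-1.95 ± 0.06, adjusted p = 0.0247) and the translocon subunit SEC61B (-1.88 ± 0.10). BMF, a promoter of apoptosis, rose by 1.95 ± 0.25 and EFNA1, a ligand of Eph receptors, by 1.80 ± 0.23. The muscle genes TAGLN (1.70 ± 0.14) and MYL9 (1.43 ± 0.19) rose with this strand as well.

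Other genes that rose were the glucose bisphosphate synthase PGM2L1 (1.85), the disulfide isomerase PDIA5 (1.55), the secreted Wnt modulator DKK3 (1.54), the AMP kinase subunit PRKAB2 (1.53) and CACFD1 (1.44). A probe annotated as the mitochondrial gene COX1 rose by 1.93, but the file places it on chromosome 1 from 567567 to 567626. Further decreases were those of the lamin-processing protease ZMPSTE24 (-1.85), the ciliary protein TCTN3 (-1.82), the RNA-binding protein HNRNPAB (-1.80), PABIR2 (-1.80) and the iron-sulfur assembly factor CIAO2B (-1.80). On hg19 the probe of GPN3 lies on chromosome 12 from 110890406 to 110890465 and that of BMF on chromosome 15 from 40380450 to 40380509. Of 21056 genes tested with both strands, 28 passed with both: 11 rose with both, 12 fell with both and 5 moved in opposite directions. This overlap was not tested, and any mock RNA that the arrays of a line had in common would add to it. Of the 198 called named genes with another measured probe, 33 had a probe with the opposite sign.

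Reported miR-145-3p targets fell, with medians of -0.92 in A549 and -0.73 in TE8 (adjusted p = 5.05e-09, and adjusted p = 0.914 with an estimated correlation). All 8 members had means under 0, 3 fell over all genes and 6 when adjusted over the list alone. The metastasis-associated MTDH (-1.45 ± 0.16) and the DNA methylation reader UHRF1 (-1.44 ± 0.21) were among those that fell. After subtraction of the treatments in other lines the median was -0.011 (adjusted p = 0.0894), or -0.39 with the miR-223-5p array left out of the mean (adjusted p = 0.00109), and 5 of the 8 members are proliferation genes. As miR-145-5p minus miR-145-3p the list did not pass (median 0.14, cameraPR adjusted p = 0.741). Its medians in that difference were 0.30 in A549 and -0.095 in TE8, so the decrease was not shown to be particular to miR-145-3p.

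Mitosis genes (median -0.49, adjusted p = 7.36e-07) and DNA replication genes (median -0.52, adjusted p = 2.16e-06) fell, each with an adjusted p = 0.914 with an estimated correlation. UHRF1 and the polymerase alpha subunit POLA2 (-0.66 ± 0.08) passed over all genes, the same 2 replication genes as the list alone counts, and 3 mitosis genes fell when adjusted over the list alone. MAD2L1, a spindle checkpoint protein, had a mean of -1.37 and an adjusted p of 0.0509. The subtraction turned these medians to 0.37 and 0.21, but with the miR-223-5p array left out of the mean they were -0.16 and -0.21 and did not pass (adjusted p = 0.145 and 0.197). As miR-145-5p minus miR-145-3p the mitosis list had a median of 0.0022 (cameraPR adjusted p = 0.924). The DNA replication list had one of -0.096 (cameraPR adjusted p = 0.789), with 0.28 in A549 and -0.53 in TE8. These decreases were thus not shown to be particular to either strand. The replication-dependent histones fell with a median of -0.40 (adjusted p = 1.95e-04, and adjusted p = 0.914 with an estimated correlation). H2AC6 fell by 1.08 ± 0.16, 1 of 11 tested members fell over all genes and 6 when adjusted over the list alone.

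Genes of the extracellular matrix rose, with medians of 0.78 in A549 and 0.23 in TE8 (adjusted p = 0.00166, and adjusted p = 0.914 with an estimated correlation). 3 of 30 rose over all genes and 7 when adjusted over the list alone: the protease inhibitor TIMP3 by 1.04 ± 0.14, the collagen crosslinker LOX by 0.78 ± 0.10 and the gelatinase MMP2 by 0.63 ± 0.07 passed over all genes. The mock signal of LOX was near background in A549, where LOX was at least 1.44-fold higher. The collagen gene COL1A1 had values of 2.32 in A549 and 0.91 in TE8 and an adjusted p of 0.0996.

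Proteins of the microRNA pathway rose as a list (median 0.15, adjusted p = 0.0287, and adjusted p = 0.914 with an estimated correlation), with 2 of 13 members called by either adjustment. DICER1, which cuts microRNA precursors, rose by 1.17 ± 0.10 (adjusted p = 0.0294) and the silencing scaffold TNRC6C by 0.66 ± 0.09. Without TE8 the list had an adjusted p of 0.278, the 4 other scalings gave 0.0985 to 0.258, and after subtraction of the treatments in other lines a median of 0.012 and an adjusted p of 0.728.

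With median centring in place of loess, at which the median of all genes was 0.40, 6077 genes were called higher and 41 lower, against 264 and 319. No gene passed without A549, without TE8, with the 2 miR-145-3p arrays fitted alone, with the scanner software's ratio or after the subtraction, and 262 passed with no filter on dim probes, 346 with an intensity trend and 215 with an offset of 1.

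The direct comparison of the 2 strands within a cell line cancels any effect common to both transfections. No gene of 21056 passed limma's test, with 4202 at an unadjusted p under 0.05 and a lowest adjusted p of 0.0616. The values nearest to the threshold were those of CEND1 (2.90 ± 0.08, as miR-145-5p minus miR-145-3p) and of the fucosidase FUCA2 (-2.23 ± 0.06). FSCN1 stood at -3.47 ± 0.30 at an adjusted p of 0.0788, and the Wnt antagonist DKK1 was 2.78 ± 0.40 higher at 0.0881. The other values named by the fixed rule were GPN3 (2.33), the proton pump subunit ATP6V0E1 (2.07), the differentiation inhibitor ID2 (2.49), TMEM9B (-2.31), the secreted protein FAM3C (-2.40) and SIRPA (-2.36).

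Reported miR-145-5p targets fell relative to miR-145-3p in both lines, with medians of -0.56 in A549 and -0.66 in TE8 (adjusted p = 5.72e-09, and adjusted p = 0.914 with an estimated correlation). No member passed over all genes, and 20 of 34 were lower when adjusted over the list alone, with the TGF-beta receptor TGFBR2 at -1.99 and the calcineurin subunit PPP3CA at -1.69. Matrix genes were lower with miR-145-5p than with miR-145-3p (median -0.49, adjusted p = 0.00272, and adjusted p = 0.914 with an estimated correlation). When adjusted over the list alone 9 of 25 were lower and 1 higher. The urokinase PLAU had a mean difference of -1.78 and the collagen gene COL1A1 of -1.74, at adjusted p of 0.0967 and 0.230 over all genes. Against mock the median of the matrix list was 0.086 with miR-145-5p and 0.63 with miR-145-3p, so it did not fall below mock.

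Interferon-stimulated genes rose relative to miR-145-3p (adjusted p = 0.00236, and adjusted p = 0.929 with an estimated correlation), with a median of 2.85 in A549 and of -0.033 in TE8, where the adjusted p without A549 was 0.897. OASL, an antiviral protein, was 5.33 in A549 and 0.083 in TE8. The hypoxia and glycolysis list passed as higher (median 0.19, adjusted p = 0.00616, and adjusted p = 0.957 with an estimated correlation), but its medians were -0.20 in A549 and 0.41 in TE8, and 11 members were higher and 9 lower. It had lactate dehydrogenase LDHA at 0.94 and enolase ENO2 at 0.83, 5 of 20 higher and 1 lower when adjusted over the list alone, and an adjusted p of 0.962 without TE8. Genes of N-glycosylation were lower with miR-145-5p than with miR-145-3p (median -0.16, adjusted p = 0.0123, and adjusted p = 0.914 with an estimated correlation). The medians of this difference were -0.30 in A549 and -0.066 in TE8. The magnesium transporter MAGT1 stood at -1.47 and PMM2 at -0.86, with 3 of 39 lower and 1 higher when adjusted over the list alone. Against mock the list median was -0.10 with miR-145-5p and 0.0039 with miR-145-3p. 72 genes passed without background correction, 2 without the cell line in the model and 1 with an intensity trend.

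**Figure D2:**
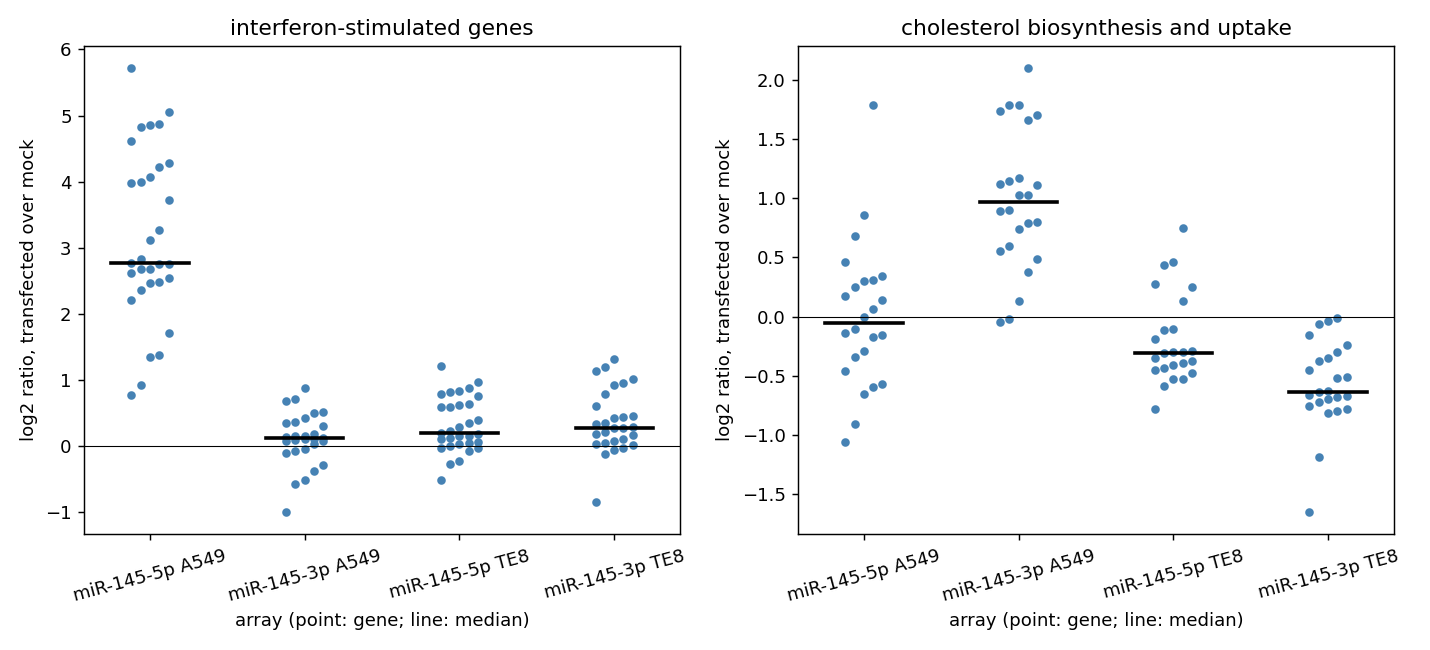
Log2 ratio of transfected over mock for each tested member (points) of the interferon-stimulated (left) and cholesterol (right) lists on the 4 miR-145 arrays, with list medians as lines. The interferon median was 2.77 with miR-145-5p in A549 and between 0.12 and 0.28 on the other arrays, and the cholesterol median was 0.96 with miR-145-3p in A549 and -0.63 with it in TE8.

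The si-PMM2 comparison asked what followed knockdown of phosphomannomutase 2, which makes the mannose 1-phosphate used in N-glycosylation, in A498 cells. PMM2 itself stood at -1.04 on both arrays (mean -1.04 ± 0.08, n = 2 arrays), which is 48.7% of mock on the scale with the offset, at an adjusted p of 0.231. With the scanner software's ratio its mean was -1.34. PMM2 ranked 5 by p among 20199 genes. Its probe lies on chromosome 16 from 8942790 to 8942849 of hg19. No gene passed limma's test under any setting tried, with 1599 at an unadjusted p under 0.05 and a lowest adjusted p of 0.231.

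The genes that the fixed rule named are given as values. The growth inhibitor BTG2, a p53 target, had a mean of 1.79 ± 0.19, with 1.43 for siRNA 1 and 2.15 for siRNA 2. The lipid transporter ABCA12 stood at 1.07, the cell cycle kinase CDK6 at 0.93, the chromatin protein HMGA2 at 1.06 and SPACA6 at 0.87. The G protein subunit GNG12 stood at -1.48 ± 0.11, PSAT1 at -1.16, the p53 effector PERP at -1.05 and the vesicle protein RAB18 at -1.01. 2 genes reached 1 and 4 reached -1 on both arrays.

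The p53 targets rose as a list (medians 0.36 for siRNA 1 and 0.40 for siRNA 2, adjusted p = 3.54e-09, and adjusted p = 0.914 with an estimated correlation). 20 of 22 had means above 0, none passed over all genes and 4 did when adjusted over the list alone. TP53I3, the ferredoxin reductase FDXR and the apoptosis gene BBC3 had values of 0.36, 0.59 and 0.56 with siRNA 1 and of 1.51, 1.203 and 1.01 with siRNA 2. After subtraction of the treatments in other lines the list median was 0.47 (adjusted p = 1.54e-15). The ATF4 list fell (medians -0.15 and -0.20, adjusted p = 9.36e-06, and adjusted p = 0.914 with an estimated correlation), with asparagine synthetase ASNS at -1.09 and the serine synthesis enzyme PHGDH at -0.87. 3 of its 21 members fell when adjusted over the list alone, and after the subtraction its adjusted p was 0.728.

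Proliferation genes had unlike values with the 2 siRNAs, a difference that was not tested. DNA replication genes fell (adjusted p = 9.67e-11) with medians of -0.85 for siRNA 1 and -0.13 for siRNA 2. Mitosis genes fell (adjusted p = 4.45e-10) with medians of -0.999 and 0.0049, and without siRNA 1 the adjusted p was 0.754. Both had an adjusted p = 0.914 with an estimated correlation, and no member passed over all genes or when adjusted over the list alone. The helicase subunit MCM7 had -1.53 and -0.23, and the mitotic kinase CDK1 had -1.33 and -0.33. After the subtraction the medians were 0.30 and 0.32, with adjusted p of 1.20e-04 and 5.71e-05, which rested on the miR-223-5p array. With that array left out of the mean they were 0.018 and 0.032 (adjusted p = 0.783 for both).

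The reported miR-145-3p targets fell as well (median -0.50, adjusted p = 4.35e-06, and adjusted p = 0.914 with an estimated correlation), with 2 of 8 members lower when adjusted over the list alone, UHRF1 at -0.89 and LMNB2 at -0.50, and an adjusted p of 0.0629 without siRNA 1. After the subtraction their median turned to 0.31 (adjusted p = 0.00292), or 0.20 without the miR-223-5p array (adjusted p = 0.0873). The ribosomal list rose with a median of 0.056 (adjusted p = 0.0152, and adjusted p = 0.923 with an estimated correlation), no member passed over the list alone, RPS2 stood at 0.40, and without siRNA 2 the adjusted p was 0.155. The median of this list was -0.022 with the scanner software's ratio (adjusted p = 0.778) and -0.14 after the subtraction, or -0.072 without the miR-223-5p array. It did not pass without background correction (adjusted p = 0.113) or with an offset of 1 (0.0865). N-glycosylation genes, the pathway of PMM2, had medians of -0.039 and -0.045 and did not pass (adjusted p = 0.346), and 1 of 39 members, PMM2 itself, was lower when adjusted over the list alone. Unfolded protein response genes had a median of -0.14 and did not pass either (adjusted p = 0.286).

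In T24 cells miR-223-3p was measured on 1 array, with no replicate and no test. 34 of 23278 genes stood at or above 1 and 125 at or below -1. The lowest was STMN1, which destabilises microtubules, at -2.87, or 7.29-fold lower. Among named genes of at least median brightness it was followed by the endoplasmic reticulum protein ARL6IP1 (-2.22), the tumour suppressor NF2 (-2.19), the cell surface protein CD109 (-2.17), the electron carrier CYB5A (-2.14), CTNNAL1 (-2.12), SYAP1 (-2.11) and EPB41L1 (-2.03). The highest of these were the protease inhibitor TFPI2 (2.19), PGM2L1 (2.04), the deubiquitinase YOD1 (1.71), the decoy receptor TNFRSF11B (1.69), the glucose transporter SLC2A14 (1.65), the growth factor AREG (1.65), the matrix protein TGFBI (1.57) and NEURL3 (1.54). The probe of STMN1 lies on chromosome 1 from 26227232 to 26227291 of hg19.

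Reported miR-223-3p targets had a median of -0.45 on this array, below the 2.5th percentile of 10000 random lists of like brightness (-0.078). 21 of 27 were under 0 and 6 at or below -1: besides STMN1, the DNA repair enzyme PARP1 (-1.81), the actin-capping protein TWF1 (-1.77) and the integrin ITGA3 (-1.33) were lowest. 3 of the list's 30 genes are in the proliferation lists. DNA replication genes (-0.25) and mitosis genes (-0.27) were below their random ranges, with E2F2 and E2F1, drivers of S phase, at -1.33 and -1.32. Relative to the arrays of other lines these 2 medians turned to 0.30 and 0.22 above their random lists. MicroRNA pathway proteins were above theirs at 0.23, with DICER1 at 1.25.

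Smaller medians outside the random range were those of the unfolded protein response (0.11), matrix (0.15) and ribosomal (0.13) lists above it and of the p53 (-0.093), interferon (-0.13), NF-kB (-0.23), actin (-0.091), mesenchymal (-0.14) and renal tubule (-0.14) lists below it. The unfolded protein response, p53 and actin medians lay close to the ends of their ranges (0.111, -0.091 and -0.086). Relative to the arrays of other lines the matrix and ribosomal medians turned to -0.097 and -0.0077. The p53 targets MDM2 and CCNG1 stood at -0.78 and -1.01. With median centring in place of loess, at which the median of all genes was 0.23, 695 genes stood at or above 1 and 24 at or below -1, against 34 and 125. The scanner software's ratio gave 1064 and 620.

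The miR-223-5p array of T24 cells, also without replicate or test, had low values of proliferation genes. 145 of 23372 genes stood at or above 1 and 581 at or below -1. All 36 DNA replication genes were under 0 and 33 at or below -1 (median -1.84), and all 40 mitosis genes were under 0 and 36 at or below -1 (median -1.79). Thymidylate synthase TYMS was lowest of all at -3.56, or 11.8-fold lower. CKS1B, a subunit of cell cycle kinases, stood at -3.39, the kinetochore protein SPC25 at -3.10, the survival and cytokinesis protein BIRC5 at -3.10, the mitotic ubiquitin enzyme UBE2C at -2.99 and thymidine kinase TK1 at -2.95.

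The 14-3-3 protein YWHAQ (-2.93) and the midbody protein CEP55 (-2.92) completed the lowest named genes of at least median brightness. The highest of these were the histone H2BC12 (2.41), the keratin KRT80 (2.40), the acute phase protein SAA2 (2.16), ANKRD46 (2.08), the drug exporter ABCC3 (1.99), TGFBI (1.97), ribokinase RBKS (1.97) and the lipid carrier APOE (1.96). The probe of TYMS lies on chromosome 18 from 673276 to 673335 of hg19. Histone genes, which are counted apart from the replication list, had a median of 0.51, with H2BC5 at 1.63. Ribosomal protein genes were above 0 in all 34 cases (median 0.41), and the ATF4 list was lower (median -0.66, with PHGDH at -1.67 and SLC7A11 at -1.23).

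Interferon-stimulated genes had a median of 0.29 on the miR-223-5p array, with ISG15 at 1.11, but -0.26 relative to random lists once the arrays of other lines were subtracted, of which 1 was miR-145-5p in A549 with its median of 2.80. The reported miR-145-3p targets, mostly proliferation genes, stood at -1.81. The unfolded protein response (-0.29), p53 (-0.28), NF-kB (-0.21), hypoxia (-0.20), mesenchymal (-0.19), reported miR-145-5p (-0.13), reported miR-223-3p (-0.21) and N-glycosylation (-0.12) lists were below their random ranges. With median centring in place of loess, at which the median of all genes was 0.18, 1021 genes stood at or above 1 and 291 at or below -1, against 145 and 581, and the scanner software's ratio gave 1726 and 1538.

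**Figure D3:**
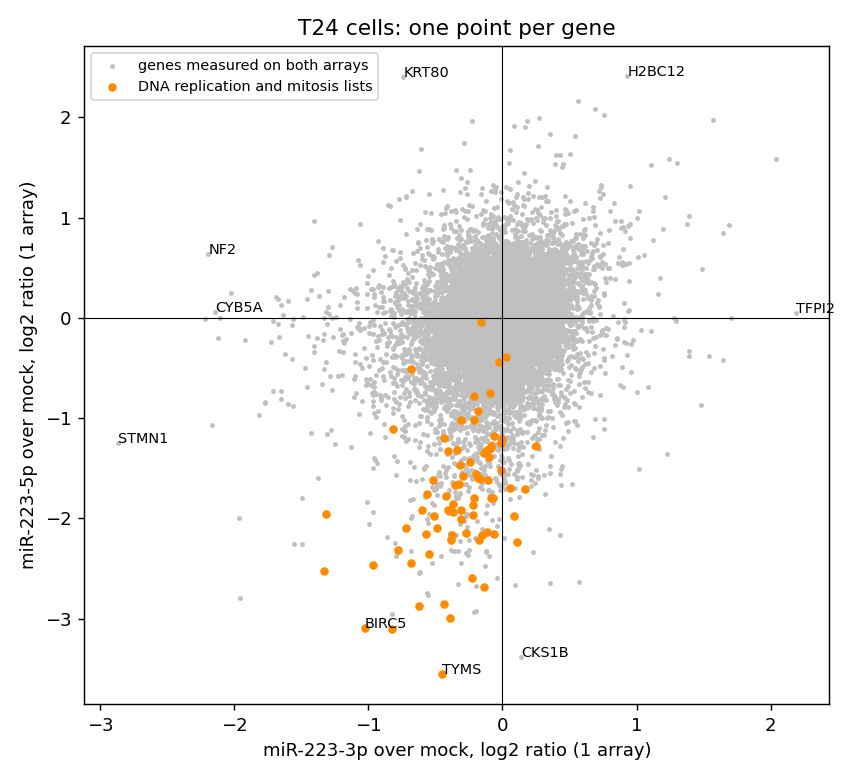
Log2 ratio of transfected over mock in T24 cells for miR-223-3p (horizontal axis) and miR-223-5p (vertical axis), 1 point per gene and 1 array per axis, with the DNA replication and mitosis lists in orange. These lists had medians of -0.25 and -0.27 with miR-223-3p and of -1.84 and -1.79 with miR-223-5p.

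Between the 2 T24 arrays, 595 of 22084 genes were at least 1 higher with miR-223-3p and 314 at least 1 lower. The median difference was 1.504 for mitosis genes, 1.43 for DNA replication genes and 1.64 for the reported miR-145-3p targets. It was also above the random range for the ATF4 (0.48), unfolded protein response (0.36), hypoxia (0.35) and reported miR-145-5p (0.12) lists. It was below it for the interferon (-0.47), histone (-0.46), ribosomal (-0.35), reported miR-223-3p (-0.26), integrin (-0.24) and renal tubule (-0.22) lists. CKS1B stood at 0.14 with miR-223-3p and -3.39 with miR-223-5p, and NF2 at -2.19 and 0.64. The scanner software's ratio gave 1774 higher and 1591 lower genes.

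**Figure D4:**
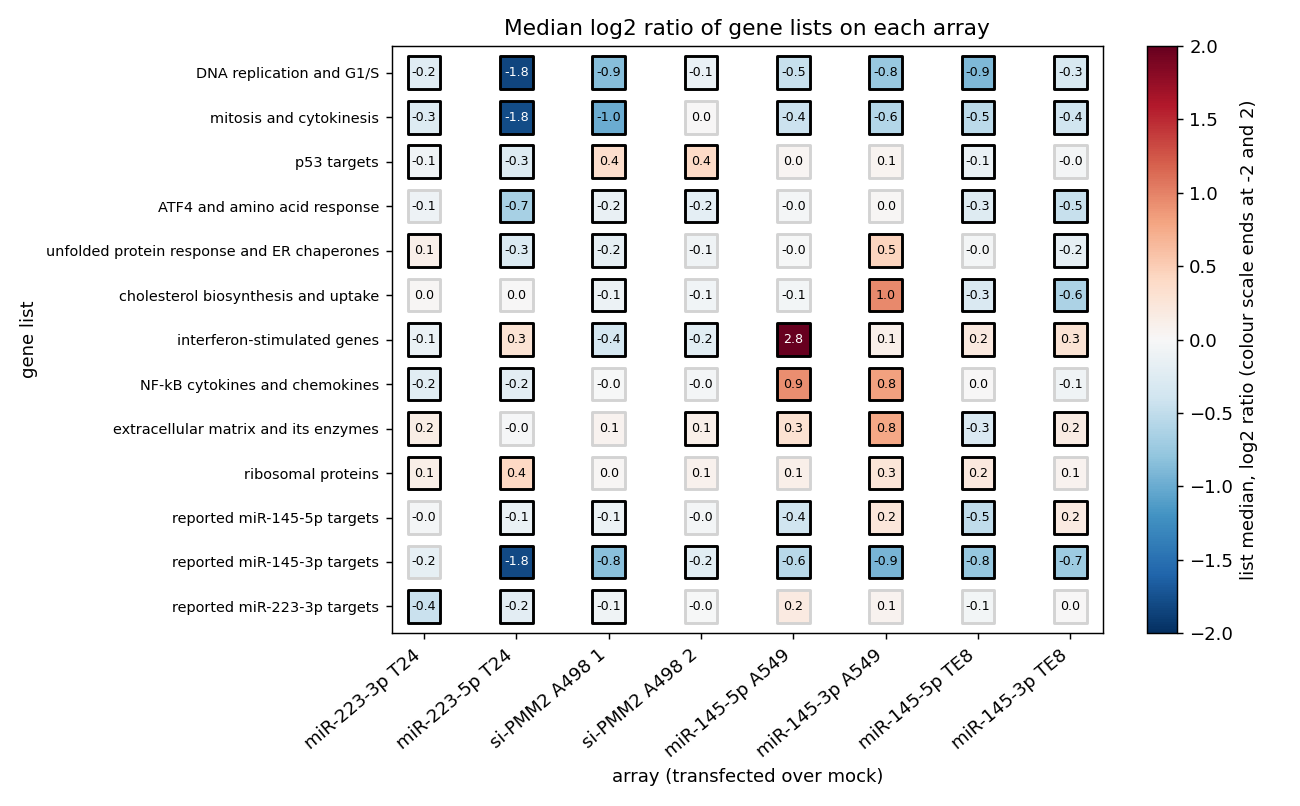
Median log2 ratio of 13 gene lists (vertical axis) on each of the 8 arrays (horizontal axis), where red is higher and blue lower than mock and a black edge marks a median outside the middle of 10000 random lists. Proliferation lists were lowest with miR-223-5p in T24, at -1.84 and -1.79, and the interferon list was highest with miR-145-5p in A549, at 2.80 over all 34 members measured there.

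Across 18241 genes measured on all arrays, the ratios of the same miR-145 strand in A549 and TE8 correlated at Pearson r = 0.42 for miR-145-5p and 0.47 for miR-145-3p (Spearman 0.38 and 0.43). These are correlations across genes, which are not independent replicates, and 28 pairs of arrays were computed. The 4 pairs of arrays of a single cell line had r from 0.24 to 0.39, and the other 22 pairs from 0.11 to 0.43. The highest of these 22 joined miR-223-5p in T24 and siRNA 1 against PMM2 in A498, at 0.43. Any mock RNA that 2 arrays of a line have in common raises their r. PMM2 was measured on every array and stood at 0.43 and -0.092 in T24 with miR-223-3p and miR-223-5p, at -0.088 and -0.30 with miR-145-5p in A549 and TE8, and at 0.74 and 0.59 with miR-145-3p.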

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

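The tests of transfection as such, of the depth of PMM2 loss and of dye bias were chosen only after the results they weigh were seen. The tests of mock signal were chosen before theirs.

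The difference TE8 minus A549 over both miR-145 strands was tested with cameraPR at the preset correlation, and the medians of the 7 lists that passed were -0.98 for NF-kB cytokines (adjusted p = 8.54e-26), -0.72 for the extracellular matrix (3.34e-13), -0.89 for cholesterol genes (2.50e-06), -0.38 for the unfolded protein response (2.19e-04), -0.28 for the ATF4 list (0.00145), -1.39 for interferon-stimulated genes (0.00559) and -0.23 for the reported miR-223-3p targets (0.0379). None of these passed with an estimated correlation (adjusted p 0.448 to 0.913), and fry called the NF-kB (0.0280), matrix (0.0189) and ATF4 (0.00211) lists. No single gene passed limma's test of this difference, with 4481 of 21056 at an unadjusted p under 0.05 and a lowest adjusted p of 0.0894. 3 lists went in opposite directions in the lines, each outside its random range on both arrays, and these differences per strand were not tested. Matrix genes with miR-145-5p stood at 0.30 in A549 and -0.30 in TE8, a difference of -0.60. Unfolded protein response genes with miR-145-3p stood at 0.45 and -0.18, a difference of -0.64, and cholesterol genes with miR-145-3p at 0.96 and -0.63, a difference of -1.595.

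Interferon-stimulated genes were high with miR-145-5p in A549 and not with miR-145-3p in that line. A response to transfection as such would raise them with both strands. Over the 28 members measured with both, the median was 0.12 with miR-145-3p (quartiles -0.051 and 0.36) against 2.76 with miR-145-5p. A response common to both transfections does not explain this gap. The same values defined the pattern, so they are no separate test, and each comes from 1 array. A lower mock signal on the miR-145-5p array is argued against by the Cy3 signal of these genes. It was 0.35 higher there (quartiles 0.067 and 1.05), where a lower one was needed. That is large beside the SD of 0.112 of the Cy3 difference between these A549 arrays over 16244 genes. Why the Cy3 signal of these genes was higher was not tested and stays open. What stays open is a response of A549 cells to miR-145-5p or to something in that transfection, which may be biological and was not tested, with 1 array of each kind.

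Mitosis genes stood at -0.999 with siRNA 1 against PMM2 and at 0.0049 with siRNA 2. Deeper loss of PMM2 is argued against by its own ratio, which differed by -0.0038 between the arrays. A dye bias of the probes that was alike on both arrays would cancel in the difference between them. The list medians differed by -1.004, with quartiles of the members' differences at -1.17 and -0.65. This gap is the pattern itself, so it is no separate test of dye bias. A higher mock signal on array 1 is argued against by a Cy3 difference of -0.028 (quartiles -0.075 and 0.018). An effect of siRNA 1 on other transcripts may remain as an explanation, which could not be tested without its sequence, and so does any difference between the cultures.

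Cholesterol genes stood at 0.96 with miR-145-3p in A549 and at -0.63 in TE8. A dye bias of the probes that was alike on both arrays would cancel in the difference of 1.595 between the lines (quartiles 1.29 and 1.91). That difference is the pattern itself, so it is no separate test of dye bias. Different mock signals on the arrays of a line are argued against by the Cy3 part of the double difference, 0.036 (quartiles -0.050 and 0.13) against 1.40 for the ratios. A difference between the lines in their response may be biological, which stays a hypothesis, as do differences in culture that the labels leave open.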

How the results depend on the processing

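The offset of 1, and for lists the other scalings and the left-out arrays, and the subtraction without the miR-223-5p array were chosen after the data were examined. The series matrix holds the scanner software's ratios, so that its counts are copies and no separate alternative. Counts are of genes, the cause of a change was not tested, and the other array is assumed to vary like the other groups where 1 is left out. For miR-145-5p (133 genes) median centring gave 2689 (2654 higher, 35 lower), 0 genes passed with the scanner software's ratio or with the series matrix, and no filter gave 6, the own arrays alone 0, subtraction of the treatments in other lines 1 and leaving out an array 0 to 170, where 28 of the 170 were among the 133. For miR-145-3p (583) these gave 6118 (6077 and 41), 0 and 0, 262, 0, 0 and 0 to 0, an intensity trend 346 and offset 1 215 (84 and 131). For the strand difference (0) no background correction gave 72 (34 and 38), an intensity trend 1 and no block 2. For si-PMM2 the count was 0 throughout.

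For miR-223-3p in T24 (159) no background correction gave 269 and median centring 719 (695 and 24). The scanner ratio gave 1684 (1064 and 620) and offset 1 gave 547 (166 and 381). For miR-223-5p (726) the same settings gave 1127, 1312 (1021 and 291), 3264 (1726 and 1538) and 1914 (628 and 1286). For the difference of the T24 arrays (909) no background correction gave 1376, the scanner ratio 3365 (1774 and 1591) and offset 1 2223 (1288 and 935). Median centring moved the median of all genes to 0.33, 0.40, 0.23 and 0.18 for miR-145-5p, miR-145-3p, miR-223-3p and miR-223-5p. With loess these medians were 0.016, 0.023, 0.015 and 0.021.

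Of the 25 list calls, 0 were kept with an estimated correlation (adjusted p 0.914 to 0.957), while fry called 2 lists, neither among the 25. Calls were also lost where the estimated correlation was below the preset 0.01. It was -0.0019 for reported miR-145-5p targets in the strand difference and -0.044 for the microRNA pathway in miR-145-3p. The losses of these lists therefore cannot be laid to correlation among genes alone. For lists with a high estimated correlation, such as 0.77 for mitosis genes with miR-145-5p, the preset may account for the call. With the subtraction 14 lists passed, and 10 of 20 calls turned: in si-PMM2 DNA replication 0.30, mitosis 0.32, ribosomal -0.14 and reported miR-145-3p targets 0.31; in miR-145-5p ATF4 0.23, DNA replication 0.15, mitosis 0.38 and ribosomal -0.017; in miR-145-3p DNA replication 0.21 and mitosis 0.37. With the miR-223-5p array left out of the subtracted mean 13 lists passed, and 4 of 20 calls turned, in si-PMM2 alone: DNA replication 0.018, mitosis 0.032, ribosomal -0.072 and reported miR-145-3p targets 0.20. No background correction and offset 1 each lost 4 calls, those of the ribosomal list in si-PMM2, ATF4 and p53 in miR-145-5p and the microRNA pathway in miR-145-3p. In T24 the subtraction turned 5 of 28 list medians, relative to random lists: with miR-223-3p DNA replication 0.30, mitosis 0.22, matrix -0.097 and ribosomal -0.0077, and with miR-223-5p interferon -0.26. Raw medians turned in 17 of 28 T24 lists with median centring, and 0 did relative to random lists. The ribosomal list of si-PMM2 was -0.022 with the scanner ratio, and the interferon list of the strand difference -0.033 without A549 (adjusted p = 0.897) and 2.85 without TE8. Of 60 named genes of the replicated comparisons none changed sign. The rule had required like signs on both arrays, so leaving out an array could not turn one. All 40 calls among the 60 were lost with the arrays of a comparison alone and with the scanner software's ratio. After subtraction of the treatments in other lines 39 were lost. The mean r of a strand between lines was 0.45 and ran from 0.42 to 0.47 over its alternatives. PMM2 stood at -1.34 with the scanner ratio.

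Not run were the 3' untranslated region searches and their alternatives, a slide term, since 1 slide held all arrays, and other PMM2 probes, since the array has 1. Where a channel was near background, a ratio is only a bound.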

Other observations

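The test of sites in probe sequences was added after the data were examined, with what it should show written before its result was seen. The genes of siRNA 1 and siRNA 2 named below were chosen after their values were seen.

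In A549 cells NF-kB cytokines were high with both miR-145 strands, with list medians of 0.93 and 0.77, and stood at 0.033 and -0.15 in TE8. The chemokine CXCL1 stood at 4.24 with miR-145-3p, the apoptosis inhibitor BIRC3 at 3.11 with miR-145-5p, and RELB, a subunit of NF-kB, at 2.32 with miR-145-5p and 1.73 with miR-145-3p. CCL20 was at least 5.41-fold higher with miR-145-3p, its mock signal being near background. In TE8 cells 7 of 16 markers of squamous epithelium stood at or above 1 with miR-145-3p (median 0.67, above the random range, whose upper end was 0.20): the desmosomal cadherin DSG3 was 1.75 and the keratins KRT6A, KRT5 and KRT6B were 1.71, 1.66 and 1.47. With miR-145-5p their median in TE8 was 0.11, within the random range. TE8 is an esophageal line, so these are genes its own tissue expresses.

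With miR-145-3p in A549, 12 of 24 cholesterol genes stood at or above 1, with the sterol sensor INSIG1 at 2.10 and DHCR7 and SQLE at 1.79 and 1.78, and the stress-induced chaperone DNAJB9 stood at 2.42. In TE8 the same strand gave CYP51A1 at -1.18 and SDF2L1 at -1.52. The matrix protein TNC stood at 2.80 with miR-145-3p in TE8. In A498 cells the heme oxygenase HMOX1 stood at 3.75 and the histone H2AZ2 at -3.01 with siRNA 2, against 0.59 and -0.34 with siRNA 1, while the disulfide protein TMX1 stood at -2.40 with siRNA 1 and 0.055 with siRNA 2. Interferon-stimulated genes were low with both siRNAs, at -0.35 and -0.23, below all 10000 random lists, and did not pass cameraPR (adjusted p = 0.239).

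Lists that passed in no replicated comparison gave these medians for si-PMM2, miR-145-5p and miR-145-3p in turn. Integrin genes had 0.032, 0.042 and 0.14, actin genes -0.037, 0.18 and 0.25, epithelial markers 0.0038, -0.051 and 0.22, mesenchymal markers -0.022, -0.11 and -0.079, and reported miR-223-3p targets -0.14, -0.015 and -0.0071. Cholesterol genes had -0.0095, -0.14 and 0.18, NF-kB cytokines -0.0041, 0.60 and 0.22 and unfolded protein response genes -0.14, -0.061 and 0.11. Leukocyte markers had 0.078, 0.034 and 0.038, squamous markers 0.061, 0.067 and -0.048 and renal tubule markers 0.061, -0.0026 and 0.034. Lung markers had 0.039 and 0.098 and urothelial markers 0.24 and 0.11 with the miR-145 strands, and too few of these were measured in A498. Fry, in contrast to cameraPR (adjusted p = 0.329), called actin genes lower with miR-145-5p than with miR-145-3p (adjusted p = 0.0344), although the median difference was 0.020, the mean -0.18 and 12 of 23 members were higher, and urothelial markers higher with miR-145-5p (0.0327). The endothelial list had too few measured members on any array.

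A hypothesis was that genes whose array probe itself holds a 7-base site for the transfected strand are lowered by pairing with that strand. Their median was below the 2.5th percentile of random lists on 6 of 6 microRNA arrays for the strand transfected, and for 2 of 26 other pairs of array and strand. It was -0.081 in both A549 and TE8 with miR-145-5p, -0.031 and -0.065 with miR-145-3p, -0.069 with miR-223-3p and -0.054 with miR-223-5p. The 2 others were sites of miR-145-5p on the miR-223-3p array (-0.019) and on that of siRNA 2 (-0.024). This is consistent with pairing, but the shifts are small and probes cover a small part of each transcript.

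Arrays of a line had Cy3 signals that differed with an SD of 0.085 to 0.112 over 16244 genes, against 0.69 to 0.79 between lines. A simulation of a single mock RNA with no real effect in common gave r of 0.48 to 0.55, against 0.24 to 0.39 observed. It gave mock and transfected RNA the same spread per gene, taken from the difference of the 2 arrays. That choice fixes the simulated r, so the comparison cannot say whether arrays of a line had a mock in common.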
